A study of Mus musculus with 15 samples.

How the data were processed

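Total RNA libraries of mouse colon were read as 76-base paired ends, from 6 groups made by 3 *Tert* genotypes (WT, VAA and KO) and 2 treatments (untreated and DSS), per the labels. Groups were taken from the sample labels, with 2 untreated and 3 DSS libraries per genotype and 15 libraries in all. The deposited files held 0 columns of other samples. The mice were 8 to 12 weeks old, per the labels' protocols.

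The authors deposited estimated counts per gene symbol, and kallisto 0.46 and the mm10 genome build are named per the submitters' processing notes. The transcript annotation and the way transcripts were summed to genes are not given in the sources used here. The deposited estimated counts were whole numbers already, so rounding changed none of them. The authors also deposited log2 CPM for 17531 genes, with the same tool and build per the submitters' processing notes. Recomputing these log2 values from the deposited counts with a prior count of 2 and no scaling factor gave values within 0.017. The count table held 32544 symbols, of which 8053 were at 0 in every library. A symbol was found in the reference annotation for 31435 of them, and 31400 had a place in GENCODE on mm10. Identical values in every library with over 50 counts were found for 35 genes, and 3 of these took between 4.145% and 13.59% of a library.

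Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter over the 6 groups, which left 17477. Libraries were scaled by trimmed mean of M values, and 1 mean per group was fitted over the 15 libraries by quasi-likelihood with 9 residual degrees of freedom, a common dispersion of 0.0457 and 4.31 prior degrees of freedom. Each of 12 comparisons was a contrast of these means: DSS against untreated in each genotype and averaged over genotypes, the 3 genotype pairs under DSS and untreated, and 2 interactions. A gene was called at a Benjamini-Hochberg adjusted *P* under 0.05, adjusted within a comparison over the genes tested. CPM values computed here are counts divided by the library total in M and by the library's trimmed mean factor. Fold changes are log2 and are given with the standard error of the fit. Where a group held 1 to 3 counts in total, the ratio of scaled counts with an exact 95% counting interval is given. A list median is given also with members whose lower group held 3 counts or fewer set to a floor of 3 counts over the group.

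There were 35 lists of 684 genes written from general knowledge, with 645 genes tested. Lists were tested by camera in limma 3.58.1 at a preset correlation between genes of 0.01 and again with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of a comparison. Members were counted by the gene test adjusted over the genes tested and again adjusted over the list alone. Genes were named by a rule: *Tert* first, then per comparison the 5 highest and 5 lowest called genes with a mean log2 CPM of at least 2, with groups that did not overlap where 2 groups were compared, and up to 4 members of a called list or 2 of another by smallest *P*, with *Mb21d1* and *Tmem173* in each genotype comparison. Predicted gene models, immunoglobulin and T cell receptor genes were left out of the highest and lowest. Many results, called lists among them, are not reported here.

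Library totals ran from 10.6 to 17.5 M counts. Between replicates the chi-square per degree of freedom of the counts ran from 10.86 to 103.8, so the spread was well above counting error. The script was tested on simulated data made from the real means and library sizes of 17477 genes, with 50 genes changed at each of 4 fold sizes. In the simulated KO against WT comparison under DSS edgeR recovered 9 of 50 genes at 1.5-fold, 22 at 2-fold, 45 at 4-fold and 49 at 8-fold, with 11 unchanged genes called. In the simulated untreated VAA against WT comparison it recovered 0, 20, 32 and 45, with 2 unchanged genes called. In the simulated KO interaction it recovered 0, 2, 37 and 43, with 3 unchanged genes called.

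Alternatives set before the data were examined were DESeq2 size factors, no expression filter, the DESeq2 1.42.0 test, limma on the deposited log2 values, a fit of only the groups compared, the replicate number as a block, sex as a covariate, and each library left out in turn. Chosen after seeing the data were a fit without both male libraries, library quality weights from limma, and KO against WT averaged over treatments for genes near *Tert*. The labels do not say that equal replicate numbers share a litter, cage or day. Over 33 pairs of libraries with equal numbers the correlation of residuals ran from -0.16 to 0.31, 8 pairs were over 0.1, and 7 of 15 libraries were closest to one of their own number, so the samples were not treated as paired. Sex was read from *Ddx3y* and other Y-linked genes. Raw reads were not used here, so transcript isoforms, the engineered alleles and reads of other organisms were not analysed here. Random draws used seed 20240.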

Results

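RNA sequencing of mouse colon was compared between 3 *Tert* genotypes with and without experimental colitis. *Tert* encodes the reverse transcriptase subunit of telomerase. The genotypes were wild type (WT), a knock-in allele whose product is enzymatically inactive by the series description (VAA), and a knockout (KO). Each genotype had 2 untreated libraries and 3 libraries after dextran sulfate sodium (DSS), a polymer that injures the colonic epithelium. DSS was given at 3% for 4 days, plain water followed for 4 days, and colon was taken on day 8. Library totals in M counts were 14.16 and 14.19 (WT untreated), 13.42 and 11.83 (VAA untreated), 14.36 and 14.22 (KO untreated), 13.87, 13.07 and 16.42 (WT DSS), 16.07, 17.54 and 10.56 (VAA DSS), and 13.91, 15.25 and 14.66 (KO DSS). Of 32544 genes listed, 17477 passed the expression filter and were tested. The labels give separate samples within a group but do not state separate animals, so the *P* values measure the spread between these samples. The rule for naming genes, the gene lists and the comparisons were set before the data were examined.

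*Tert* was read first in every library as a check of the genotype labels. The gene lies on chromosome 13 from 73626911 to 73649843 on the plus strand of mm10. WT libraries held 37 and 40 *Tert* counts untreated and 26, 36 and 23 under DSS. VAA libraries held 25 and 15 untreated and 29, 12 and 7 under DSS, whereas KO libraries held 1 and 1 untreated and 0, 0 and 1 under DSS. The KO level of *Tert* was 2.6% of WT (95% interval 0.309 to 9.71) untreated and 1.25% (0.0314 to 7.18) under DSS. The VAA level was 59.6% of WT (39.6 to 88.4) untreated and 55.7% (38.3 to 80.2) under DSS. These intervals cover counting error only. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, *Tert* fell in KO against WT under DSS, with 1 count against 85, a ratio of 79.7 (13.9 to 3190), adjusted *P* = 0.0019. Untreated, the ratio of *Tert* in WT to KO was 38.5 (10.3 to 323) with a Benjamini-Hochberg adjusted *P* = 0.27 by the same edgeR test. For *Tert* in VAA against WT the edgeR log2 fold change was -0.91 ± 0.44 (SE) under DSS and -0.76 ± 0.53 untreated, with Benjamini-Hochberg adjusted *P* of 0.32 and 1. The part of the gene that was deleted is not given in the sources used here.

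Treatment was the largest source of variation between libraries. Principal component 1 carried 45.8% of the variance and component 2 carried 19.3%. Untreated libraries lay between -65.8 and -53.5 on component 1, WT and VAA DSS libraries between 41.0 and 63.8, and KO DSS libraries between 10.5 and 15.2. VAA DSS replicate 3 lay apart at 102 on component 2. That library was also the shallowest, with 10.56 M counts, and 13.59% of its counts lay in 3 genes with identical values. The Y-linked RNA helicase gene *Ddx3y* had 914 counts in WT untreated replicate 2 and 868 in KO untreated replicate 2, against 5 to 20 in each of the other 13 libraries. Thus 1 of the 2 untreated WT libraries and 1 of the 2 untreated KO libraries were male, and every DSS library was female.

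**Figure D1:**
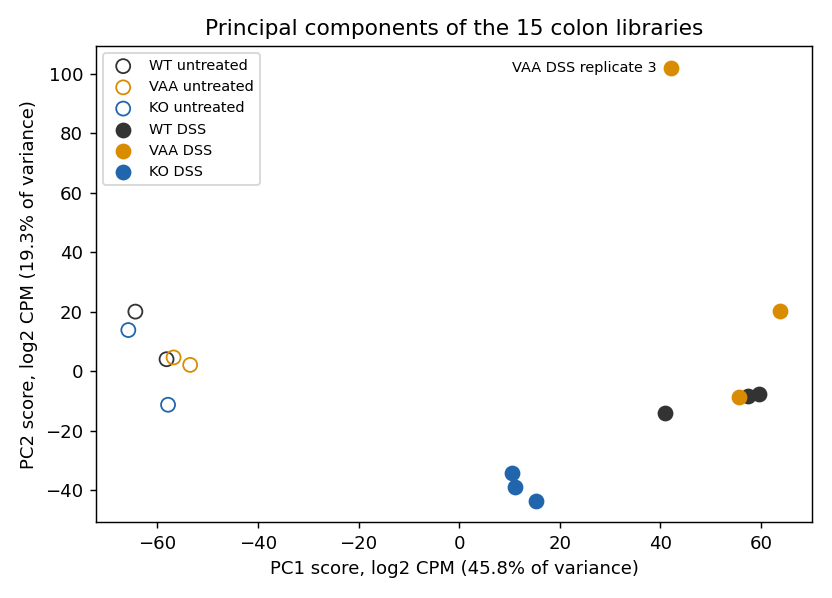
Principal components 1 and 2 of log2 CPM, in arbitrary units, with 1 point per library, coloured by genotype, filled for DSS and open for untreated. KO DSS libraries lay at 10.5 to 15.2 on component 1 against 41.0 to 63.8 for WT and VAA DSS libraries, and VAA DSS replicate 3 lay at 102 on component 2.

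DSS against untreated WT colon asked which transcripts changed in colitis when *Tert* was intact (n = 3 and 2). *S100a9* and *S100a8*, which encode the calprotectin subunits, had 3192 counts against 1 and 2982 against 3, ratios of 2150 (95% counting interval 386 to 85100) and 671 (229 to 3250). *Chil3*, a chitinase-like gene of myeloid cells, had 1770 counts against 1, a ratio of 1190 (214 to 47200). *Nos2*, the inducible nitric oxide synthase, rose by 7.72 ± 0.55 log2 units. *Acod1*, the itaconate-producing enzyme of macrophages, rose by 7.94 ± 1.07, and WT untreated replicate 1 held 0 counts of it, so without WT untreated replicate 2 no fold can be given. Among the genes that fell most, *Mptx1*, a mucosal pentraxin, changed by -7.95 ± 0.75, *Cyp2c55*, a cytochrome P450, by -6.21 ± 0.83, and *Tppp3*, a tubulin-binding protein gene, by -4.25 ± 0.46. *Tmem173*, which encodes STING, rose by 2.16 ± 0.31, and *Mb21d1*, which encodes cGAS, changed by 0.77 ± 0.37 with an edgeR Benjamini-Hochberg adjusted *P* = 0.14. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2466 genes were higher and 2176 lower, and *Acod1*, *Cyp2c55* and *Tmem173* had adjusted *P* of 0.00024, 0.00023 and 0.00037. The count of 4642 genes was 1958 without WT untreated replicate 1, 2176 without WT untreated replicate 2 and 2842 without WT DSS replicate 2.

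Neutrophil markers had the highest list median in WT colitis, with 17 of 20 rising and 3 not passing (18 adjusted over the list alone), at a median of 5.30, or 4.65 with 8 members set to their floor. Inflammatory cytokine genes followed, 20 of 26 with 6 not passing (24 adjusted over the list alone), at a median of 3.89, or 3.75 with 6 members at their floor. Among them *Il1b*, the interleukin-1 beta gene, rose by 6.47 ± 0.55 and *Cxcl5*, a neutrophil-attracting chemokine, by 4.26 ± 0.46. Of 17 epithelial antimicrobial genes, 12 rose and 5 did not pass (12 rose and 1 fell adjusted over the list alone), at a median of 2.89, with *Lcn2*, the iron-binding lipocalin, at 6.34 ± 0.60. Of 15 smooth muscle genes, 15 fell (15 adjusted over the list alone) at a median of -2.58, with *Actg2*, the enteric smooth muscle actin, at -3.79 ± 0.51. Of 23 genes of the cGAS STING pathway, 8 rose, 1 fell and 14 did not pass (10 rose and 1 fell adjusted over the list alone), at a median of 0.568. By camera with Benjamini-Hochberg adjustment the neutrophil list had *P* = 3.3e-32 at the preset correlation and adjusted p = 0.008 with an estimated correlation. The same Benjamini-Hochberg adjusted camera values were 4.6e-17 and 0.027 for cytokines and 2.1e-11 and 0.013 for antimicrobial genes. Smooth muscle genes had a camera Benjamini-Hochberg adjusted *P* = 3e-15, and adjusted p = 0.24 with an estimated correlation. The cGAS STING list had a camera Benjamini-Hochberg adjusted *P* = 0.0031, and adjusted p = 0.34 with an estimated correlation.

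DSS against untreated VAA colon asked the same of colon with the inactive enzyme (n = 3 and 2). *S100a8* had 4322 counts against 3, a ratio of 836 (95% counting interval 286 to 4050), and *S100a9* rose by 8.83 ± 0.51. *Lrg1*, a secreted glycoprotein of inflamed tissue, rose by 8.51 ± 0.65, and *Plet1*, a surface marker of repairing epithelium, by 8.44 ± 0.66. *Mptx1* changed by -8.03 ± 0.75 and *Hao2*, a peroxisomal oxidase, by -4.77 ± 0.41. *Tmem173* rose by 1.99 ± 0.31, and *Mb21d1* changed by 0.66 ± 0.38 with an edgeR Benjamini-Hochberg adjusted *P* = 0.25. Of 20 neutrophil markers 20 rose (20 adjusted over the list alone) at a median of 5.48, or 5.18 with 10 members at their floor. Of 26 cytokine genes 19 rose and 7 did not pass (24 adjusted over the list alone) at a median of 3.90, or 3.53 with 8 members at their floor, and *Cxcl2*, a neutrophil chemokine, rose by 7.51 ± 0.55. The neutrophil list had a camera Benjamini-Hochberg adjusted *P* = 5e-39, and adjusted p = 0.005 with an estimated correlation. The cytokine list had a camera Benjamini-Hochberg adjusted *P* = 1.1e-19, and adjusted p = 0.015 with an estimated correlation. With Benjamini-Hochberg adjustment of edgeR's quasi-likelihood test, 1904 genes were higher and 1667 lower, and *Tmem173* had an adjusted *P* = 0.00057. In a fit of only the groups compared 1088 of these 3571 genes were still called. The count of 3571 genes was 1789 without VAA untreated replicate 1 and 2039 without VAA untreated replicate 2.

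Goblet cell genes moved in both directions in VAA colitis. Of 20, 3 rose, 10 fell and 7 did not pass (4 rose and 10 fell adjusted over the list alone), at a median of -0.892. *Clca1*, a secreted mucus-processing protein gene, changed by -3.09 ± 0.36 and *Klk1*, a tissue kallikrein, by -4.36 ± 0.39, while *Retnlb*, a bactericidal resistin-like gene, rose by 7.43 ± 0.64. The goblet list had a camera Benjamini-Hochberg adjusted *P* = 0.00032, and adjusted p = 0.36 with an estimated correlation. Regenerative epithelium genes rose in 13 of 20 with 7 not passing (13 adjusted over the list alone) at a median of 1.41, with *Ereg*, an epidermal growth factor receptor ligand, at 2.89 ± 0.35. That list had a camera Benjamini-Hochberg adjusted *P* = 8.4e-11, and adjusted p = 0.082 with an estimated correlation. The cGAS STING list rose in 5 of 23 members with 18 not passing (5 adjusted over the list alone), median 0.354, with a camera Benjamini-Hochberg adjusted *P* = 0.023, and adjusted p = 0.41 with an estimated correlation. Its call was lost without VAA untreated replicate 2 (median 0.367, Benjamini-Hochberg adjusted *P* = 0.055 by camera on the edgeR fit) and VAA DSS replicate 2 (0.288, 0.12).

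DSS against untreated KO colon asked which transcripts changed without *Tert* (n = 3 and 2). *Retnlb* rose by 7.75 ± 0.65, *Clca4b*, a chloride channel accessory gene of surface epithelium, by 7.62 ± 0.32, *Plet1* by 6.51 ± 0.61 and *Ido1*, the interferon-induced tryptophan-degrading enzyme, by 6.01 ± 0.57. *Cyp2c55* changed by -7.39 ± 0.88, *Slc30a10*, a manganese exporter, by -7.28 ± 0.44 and *Mptx1* by -4.95 ± 0.63. *S100a9* rose by 4.66 ± 0.53 and *S100a8* by 3.90 ± 0.63. *Tmem173* rose by 1.13 ± 0.30, with an edgeR Benjamini-Hochberg adjusted *P* = 0.032. That call on *Tmem173* was lost without KO untreated replicate 1 (0.91, Benjamini-Hochberg adjusted *P* = 0.24 by edgeR), KO untreated replicate 2 (1.39, 0.076), KO DSS replicate 1 (1.16, 0.061), KO DSS replicate 2 (1.13, 0.073) and KO DSS replicate 3 (1.11, 0.069). *Mb21d1* changed by 0.29 ± 0.38, edgeR Benjamini-Hochberg adjusted *P* = 0.68. After Benjamini-Hochberg adjustment of edgeR's quasi-likelihood test, 977 genes were higher and 885 lower, and *S100a8* had an adjusted *P* = 0.0025. With sex as a covariate 1071 of these 1862 genes were still called. In fits of only the groups compared DSS called more genes in KO than in VAA, the reverse of the order here. The count of 1862 genes was 403 without KO untreated replicate 1, 703 without KO untreated replicate 2, 3750 without VAA DSS replicate 3, 1040 without KO DSS replicate 1, 850 without KO DSS replicate 2 and 1024 without KO DSS replicate 3.

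Of 19 MHC class I genes 16 rose in KO colitis and 3 did not pass (19 adjusted over the list alone) at a median of 1.46, with *H2-Q7*, a nonclassical class I gene, at 2.92 ± 0.20 and *H2-D1*, a classical one, at 1.61 ± 0.15. Of 17 antimicrobial genes 7 rose and 10 did not pass (10 adjusted over the list alone) at a median of 1.66, with *Slpi*, a secreted leukocyte protease inhibitor, at 4.51 ± 0.50. Both lists had a camera Benjamini-Hochberg adjusted p = 0.025 with an estimated correlation, and 9.4e-35 and 1e-10 at the preset one. Of 20 neutrophil markers 10 rose and 10 did not pass (12 adjusted over the list alone) at a median of 2.15, or 2.07 with 5 members at their floor. The neutrophil list had a camera Benjamini-Hochberg adjusted *P* = 1.6e-10, and adjusted p = 0.094 with an estimated correlation. Of 26 cytokine genes 7 rose and 19 did not pass (9 adjusted over the list alone) at a median of 0.864, or 0.771 with 6 members at their floor, which was 2.34 without KO untreated replicate 2. The cytokine list had a camera Benjamini-Hochberg adjusted *P* = 1.5e-06, and adjusted p = 0.15 with an estimated correlation. Of 39 interferon stimulated genes 19 rose and 20 did not pass (33 adjusted over the list alone) at a median of 1.47, with a camera Benjamini-Hochberg adjusted *P* = 4.5e-16, and adjusted p = 0.29 with an estimated correlation.

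The DSS effect averaged over genotypes asked what colitis changed whatever the *Tert* allele (n = 9 and 6). *Retnlb* rose by 9.08 ± 0.44, *S100a9* by 8.09 ± 0.31, *Clca4b* by 7.57 ± 0.18 and *Plet1* by 7.25 ± 0.36. *Mptx1* changed by -6.98 ± 0.41, *Cyp2c55* by -6.68 ± 0.50, *Sycn*, a zymogen granule protein gene, by -4.74 ± 0.30, and *Hao2* by -3.98 ± 0.23. *Tmem173* rose by 1.76 ± 0.18. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3936 genes higher and 3501 lower, and *Cyp2c55* and *Tmem173* had adjusted *P* of 4.9e-07 and 5.7e-06.

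Several leukocyte and defence lists rose in the averaged DSS effect. Neutrophil markers rose in 19 of 20 with 1 not passing (20 adjusted over the list alone) at a median of 5.15, cytokines in 23 of 26 with 3 not passing (23 alone) at 2.64, and antimicrobial genes rose in 12 and fell in 2 of 17 (12 and 2 alone) at 2.57. Their camera Benjamini-Hochberg adjusted *P* values were 1.7e-31, 5.9e-17 and 4e-13, and the adjusted p = 0.01, 0.024 and 0.011 with an estimated correlation. Interferon gamma induced GTPases and related genes rose in 24 of 24 (24 alone) at a median of 2.64 and MHC class I genes in 17 of 19 (17 alone) at 1.15. For these 2 lists camera gave Benjamini-Hochberg adjusted *P* of 4e-15 and 1.7e-19, and adjusted p = 0.24 and 0.064 with an estimated correlation. Interferon stimulated genes rose in 24 of 39 with 15 not passing (27 alone) at a median of 0.769, with *Bst2*, the virus-tethering protein gene, at 1.40 ± 0.19. Genes of the cGAS STING pathway rose in 14 and fell in 2 of 23 (14 and 2 alone) at 0.447, with *Ifi205*, a DNA-binding interferon-inducible gene, at 1.96 ± 0.27. For these 2 lists camera gave Benjamini-Hochberg adjusted *P* of 0.00011 and 0.0025, and adjusted p = 0.69 and 0.28 with an estimated correlation.

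The remaining immune lists of the averaged DSS effect were less even. T and NK cell genes rose in 19 of 22 with 3 not passing (20 rose and 1 fell adjusted over the list alone) at a median of 1.95, with *Nkg7*, a cytotoxic granule protein gene, at 3.84 ± 0.36. NF-kB targets rose in 15 and fell in 1 of 20 (16 and 1 alone) at 0.626, with *Icam1*, a leukocyte adhesion molecule, at 2.26 ± 0.21. Monocyte and macrophage genes rose in 13 and fell in 2 of 20 (13 and 2 alone) at 0.73, with *Cd14*, the endotoxin coreceptor, at 1.58 ± 0.14. MHC class II genes rose in 6 and fell in 1 of 10 (7 and 1 alone) at 1.32, with *Cd74*, the invariant chain, at 1.95 ± 0.23. In that order camera gave Benjamini-Hochberg adjusted *P* of 7.3e-09, 8.9e-07, 0.00033 and 0.0035, and adjusted p = 0.22, 0.22, 0.35 and 0.61 with an estimated correlation. B cell genes had 0 of 18 members passing (0 alone) at a median of 1.09, and plasma cell genes rose in 3 and fell in 5 of 13 (3 and 5 alone) at -0.251, with the joining chain gene *Jchain* at -1.81 ± 0.17. For B cell and plasma cell lists camera gave Benjamini-Hochberg adjusted *P* of 0.13 and 0.47, and adjusted p = 0.83 and 0.69 with an estimated correlation. The B cell list was called without WT untreated replicate 2 (1.62), VAA untreated replicate 2 (1.6), KO untreated replicate 2 (1.75) or KO DSS replicate 2 (1.24), and the plasma cell median ran from -0.428 to -0.135.

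Epithelial lists of the averaged DSS effect went both ways. Regenerative epithelium genes rose in 14 and fell in 1 of 20 (15 and 1 adjusted over the list alone) at a median of 0.629, with *Plaur*, the urokinase receptor, at 2.86 ± 0.14. Proliferation genes rose in 21 of 24 with 3 not passing (23 alone) at 0.816, with *Rrm2*, a nucleotide reductase subunit, at 1.47 ± 0.22. Absorptive colonocyte genes rose in 5 and fell in 14 of 23 (5 and 15 alone) at -0.625, with *Car4*, a surface carbonic anhydrase, at -1.63 ± 0.14. Stem cell and Wnt genes rose in 2 and fell in 12 of 18 (2 and 12 alone) at -0.604, with *Znrf3*, a Wnt receptor ligase, at -0.83 ± 0.09. Camera gave these 4 lists Benjamini-Hochberg adjusted *P* of 3.9e-07, 0.00012, 0.0023 and 0.0023, and adjusted p = 0.2, 0.69, 0.24 and 0.24 with an estimated correlation. Goblet cell genes rose in 7 and fell in 10 of 20 (7 and 10 alone) at -0.513, enteroendocrine genes rose in 3 and fell in 2 of 14 (3 and 2 alone) at 0.0132, and tuft cell genes rose in 3 and fell in 4 of 12 (4 and 4 alone) at -0.117. Camera gave Benjamini-Hochberg adjusted *P* of 0.12, 0.92 and 0.7 for these, and adjusted p = 0.69, 0.96 and 0.85 with an estimated correlation. The goblet list was called without WT untreated replicate 1, WT DSS replicate 3 or VAA DSS replicate 2 (camera Benjamini-Hochberg adjusted *P* of 0.042, 0.042 and 0.029), and enteroendocrine and tuft medians ran from -0.143 to 0.0887 and from -0.237 to -0.0608. Squamous genes rose in 4 and fell in 1 of 10 (4 and 1 alone) at 0.386, with *Sprr1a*, a cornified envelope gene, at 3.32 ± 0.18. Squamous genes had a camera Benjamini-Hochberg adjusted *P* = 0.04, and adjusted p = 0.24 with an estimated correlation. The squamous call was lost without VAA untreated replicate 1 (median 0.761, Benjamini-Hochberg adjusted *P* = 0.061 by camera on the edgeR fit), VAA DSS replicate 3 (0.257, 0.12) and KO DSS replicate 2 (0.356, 0.051), and its median was 0.647 without WT untreated replicate 1 and 0.646 without KO untreated replicate 1.

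Smooth muscle genes fell in 15 of 15 (15 adjusted over the list alone) at a median of -1.84 in the averaged DSS effect, and pancreatic acinar type genes in 3 of 8 with 5 not passing (3 alone) at -0.503, with *Cela1*, an elastase, at -2.89 ± 0.15. Oxidative phosphorylation genes rose in 12 of 30 with 18 not passing (12 alone) at 0.218, with *Ndufs3*, a complex I subunit, at 0.45 ± 0.07. In that order camera gave Benjamini-Hochberg adjusted *P* of 4.7e-12, 0.00015 and 0.013, and adjusted p = 0.24, 0.024 and 0.71 with an estimated correlation. Extracellular matrix genes rose in 9 and fell in 4 of 25 (9 and 4 alone) at 0.0338, endothelial genes rose in 1 and fell in 3 of 15 (1 and 3 alone) at 0.223, adipocyte genes rose in 4 and fell in 1 of 13 (4 and 1 alone) at 0.67, and red blood cell genes fell in 2 of 7 (2 alone) at -0.853. Camera gave these 4 lists Benjamini-Hochberg adjusted *P* of 0.67, 0.67, 0.57 and 0.12, and adjusted p = 0.94, 0.94, 0.93 and 0.69 with an estimated correlation. Without VAA DSS replicate 3 the matrix and endothelial medians were -0.176 and -0.0652, and single libraries left out gave up to 0.118 and 0.354. The adipocyte median ran from 0.351 to 1.45, and red blood cell genes were called without WT DSS replicate 1 (-1.24, camera Benjamini-Hochberg adjusted *P* = 0.036). Telomerase and telomere genes rose in 7 and fell in 1 of 19 (7 and 1 alone) at 0.133, with *Nhp2*, a telomerase ribonucleoprotein gene, at 1.22 ± 0.17. Targets of p53 rose in 4 and fell in 1 of 19 (4 and 1 alone) at 0.216, fatty acid oxidation genes rose in 4 and fell in 9 of 20 (4 and 10 alone) at -0.199, and immediate early genes rose in 5 of 16 (4 alone) at 0.526. Camera gave these 4 lists Benjamini-Hochberg adjusted *P* of 0.45, 0.67, 0.1 and 0.19, and adjusted p = 0.81, 0.79, 0.69 and 0.69 with an estimated correlation. Fatty acid oxidation genes were called without WT untreated replicate 1 or KO untreated replicate 1 (camera Benjamini-Hochberg adjusted *P* of 0.047 and 0.03), and the telomerase and p53 medians ran from 0.0749 to 0.16 and from 0.143 to 0.275.

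Among the last 3 lists of the averaged DSS effect, genes on chromosome 13 near *Tert* rose in 4 and fell in 4 of 15 (4 and 4 adjusted over the list alone) at a median of 0.0196, with *Tppp*, a tubulin-binding protein gene, at -3.25 ± 0.24. Enteric neuron and glia genes rose in 1 of 18 (0 alone) at -0.224, through *Ret*, the receptor for glial cell line-derived neurotrophic factor, at 0.87 ± 0.28. The mitochondrial genome list rose in 1 of 13 (0 alone) at 0.0459, through *mt-Nd6*, a complex I subunit, at 0.27 ± 0.08. The call on *Ret* was lost without WT untreated replicate 2 (0.79), VAA untreated replicate 1 (0.82) or KO untreated replicate 2 (0.76), and that on *mt-Nd6* without WT untreated replicate 2, VAA untreated replicate 1 or KO untreated replicate 1, with edgeR Benjamini-Hochberg adjusted *P* of 0.055, 0.06 and 0.062. Camera gave the 3 lists Benjamini-Hochberg adjusted *P* of 0.57, 0.49 and 0.9, and adjusted p = 0.69, 0.93 and 0.96 with an estimated correlation. With single libraries left out the 3 medians ran from -0.0448 to 0.0936, from -0.561 to -0.0868 and from -0.0358 to 0.131. Median, mean and test differed in sign for 3 lists: the test pointed down for chromosome 13 genes (mean -0.234), for endothelial genes (mean -0.0514) and for enteroendocrine genes (mean 0.144), while each median was above 0.

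The DSS responses of the genotypes shared many genes. WT and VAA shared 1308 higher and 1172 lower genes where chance gives 269 and 208, with 1 in opposite directions. WT and KO shared 714 and 663 where chance gives 138 and 110, with 2 opposite. VAA and KO shared 646 and 511 where chance gives 106 and 84.4, with 3 opposite. The correlation of log2 fold changes across genes was 0.736 for WT and VAA, 0.686 for WT and KO and 0.557 for VAA and KO. No library was shared within any of these pairs. Genes called in both members of a pair passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in each.

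KO against WT under DSS asked how losing *Tert* changed the inflamed colon (n = 3 each). Neutrophil genes were lower. *Retnlg*, a resistin-like gene of neutrophils, changed by -5.18 ± 0.36, *S100a8* by -4.45 ± 0.33, *S100a9* by -3.80 ± 0.28 and *Clec4d*, a myeloid lectin receptor, by -3.54 ± 0.37. *Chil3* changed by -4.86 ± 0.53, *Mmp10*, a stromelysin, by -4.76 ± 0.74, and *Lcn2* by -4.61 ± 0.43. Higher were *Fabp6*, the bile acid binding protein gene, at 3.16 ± 0.45, and *Mptx1* at 3.89 ± 0.68, *Eno3*, a muscle-type enolase, at 2.54 ± 0.44 and *Tppp* at 2.17 ± 0.39, and these last 3 calls were lost without WT DSS replicate 2 (3.56, 2.35 and 1.97, Benjamini-Hochberg adjusted *P* = 0.059, 0.059 and 0.067 by edgeR). *Tmem173* changed by -0.92 ± 0.25 and *Mb21d1* by -0.64 ± 0.33, with Benjamini-Hochberg adjusted *P* of 0.052 and 0.28 by edgeR. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 561 genes were higher and 430 lower, and *Mmp10* and *Mptx1* had adjusted *P* of 0.0048 and 0.0087. The count of 991 genes was 631 without WT untreated replicate 2, 259 without WT DSS replicate 1, 121 without WT DSS replicate 2, 2704 without VAA DSS replicate 3, 236 without KO DSS replicate 1, 403 without KO DSS replicate 2 and 349 without KO DSS replicate 3.

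Neutrophil markers fell in 16 of 20 with 4 not passing (17 adjusted over the list alone) at a median of -2.99 in KO against WT under DSS. Cytokine genes fell in 17 of 26 with 9 not passing (20 alone) at a median of -2.32, with *Cxcl2* at -3.04 ± 0.32, *Il1b* at -2.74 ± 0.35 and *Osm*, the oncostatin M gene, at -2.90 ± 0.38. Camera gave the neutrophil list a Benjamini-Hochberg adjusted *P* = 3.6e-53 and the cytokine list 3e-22, and adjusted p = 0.0012 and 0.016 with an estimated correlation. MHC class I genes rose in 4 of 19 with 15 not passing (11 alone) at 0.523, with *H2-K1*, a classical class I gene, at 0.79 ± 0.12. Goblet cell genes rose in 6 of 20 with 14 not passing (9 alone) at 0.695, with *Fcgbp*, a mucus protein gene, at 1.38 ± 0.19 and *Tff3*, a trefoil factor, at 1.16 ± 0.17. For these 2 lists camera gave Benjamini-Hochberg adjusted *P* of 3.9e-09 and 5.2e-09, and adjusted p = 0.33 and 0.29 with an estimated correlation. Regenerative epithelium genes fell in 4 of 20 with 16 not passing (5 alone) at -0.409, with *Ereg* at -2.65 ± 0.29 and *Plaur* at -1.41 ± 0.19, and matrix genes fell in 6 of 25 with 19 not passing (7 alone) at -0.482, with *Mmp13*, a collagenase, at -3.85 ± 0.63. For regenerative and matrix lists camera gave Benjamini-Hochberg adjusted *P* of 3.4e-05 and 2.3e-07, and adjusted p = 0.33 and 0.49 with an estimated correlation.

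The cGAS STING list had 1 member higher and 1 lower of 23 (1 and 5 adjusted over the list alone) in KO against WT under DSS, with a median of -0.137, a camera Benjamini-Hochberg adjusted *P* = 0.21, and adjusted p = 0.69 with an estimated correlation. Its median ran from -0.239 to -0.0889 with single libraries left out, and it was called lower without WT DSS replicate 3 (-0.23, camera Benjamini-Hochberg adjusted *P* = 0.019). *Ifi205* was the lower one at -2.01 ± 0.40 with an edgeR Benjamini-Hochberg adjusted *P* = 0.014, lost without WT DSS replicate 1 (-1.45), WT DSS replicate 2 (-2.12) and KO DSS replicate 1 (-1.81). Interferon stimulated genes had 1 of 39 higher (0 alone) at a median of 0.712, with a camera Benjamini-Hochberg adjusted *P* = 4.6e-08, and adjusted p = 0.59 with an estimated correlation. The interferon stimulated median was 1.1 without WT DSS replicate 1 and 0.445 without KO DSS replicate 1. T and NK cell genes had 0 of 22 members passing (0 alone) at 0.482, with a camera Benjamini-Hochberg adjusted *P* = 0.011, and adjusted p = 0.61 with an estimated correlation, lost without WT DSS replicate 3 (0.468, 0.1). Antimicrobial genes rose in 1 and fell in 4 of 17 (2 and 5 alone), with a median of 0.00222, a mean of -0.794 and a test pointing down, camera Benjamini-Hochberg adjusted *P* = 0.019, and adjusted p = 0.38 with an estimated correlation. The antimicrobial call was lost without VAA DSS replicate 3 (Benjamini-Hochberg adjusted *P* = 0.067 by camera on the edgeR fit) and KO DSS replicate 2 (0.095), its median ran from -0.165 to 0.092 with single libraries left out, and its member *Saa3*, an acute phase protein gene, was at -3.68 ± 0.34. Monocyte and macrophage genes rose in 1 and fell in 3 of 20 (1 and 5 alone) at a median of -0.511, or -0.788 without KO DSS replicate 3, with a camera Benjamini-Hochberg adjusted *P* = 2e-04, and adjusted p = 0.49 with an estimated correlation. Smooth muscle genes had 0 of 15 passing (0 alone) at 0.559 and endothelial genes 0 of 15 (0 alone) at -0.485, with camera Benjamini-Hochberg adjusted *P* of 0.019 and 0.035, and adjusted p = 0.69 with an estimated correlation for each. The smooth muscle call was lost without WT DSS replicate 2 (0.46), KO DSS replicate 1 (0.488) or KO DSS replicate 3 (0.4), and its median was 0.892 without KO DSS replicate 2. The endothelial call was lost without WT DSS replicate 1 (-0.489), WT DSS replicate 2 (-0.365), KO DSS replicate 2 (-0.369) or KO DSS replicate 3 (-0.578). Enteric neuron and glia genes were at -1.04 and proliferation genes at -0.505 with 0 passing, with a camera Benjamini-Hochberg adjusted *P* = 0.00024 each, and adjusted p = 0.61 and 0.64 with an estimated correlation. Only the neutrophil and cytokine calls held with an estimated correlation.

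**Figure D2:**
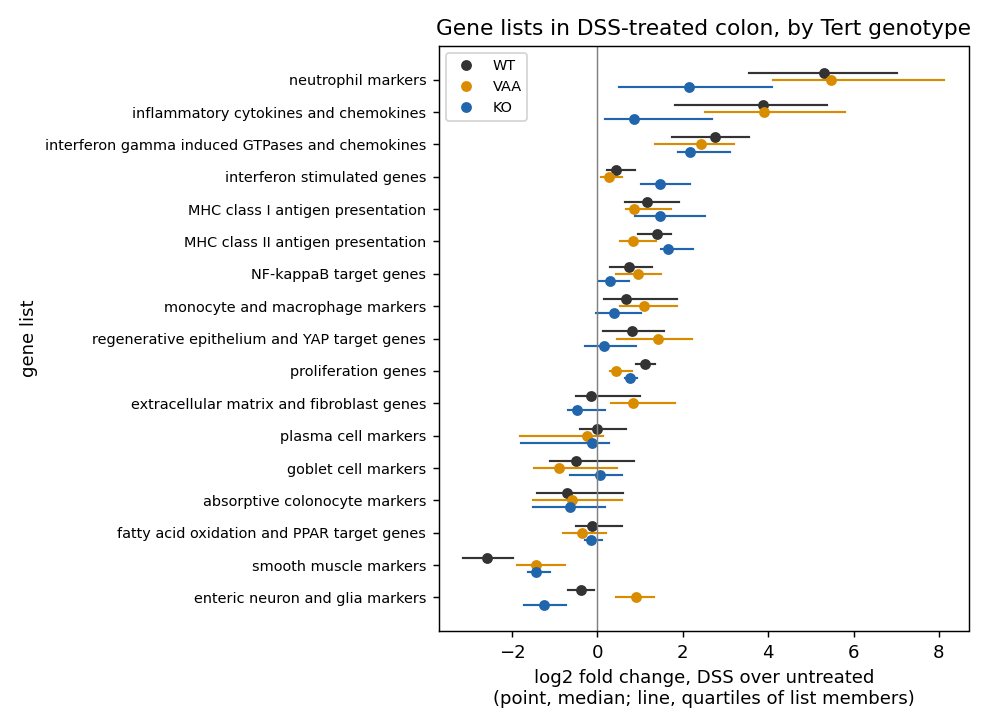
Log2 fold change of DSS over untreated in each genotype, with gene lists on the vertical axis, points as medians and lines as quartiles of list members. Neutrophil markers lay at 5.30 in WT, 5.48 in VAA and 2.15 in KO, and cytokine genes at 3.89, 3.90 and 0.864.

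**Figure D3:**
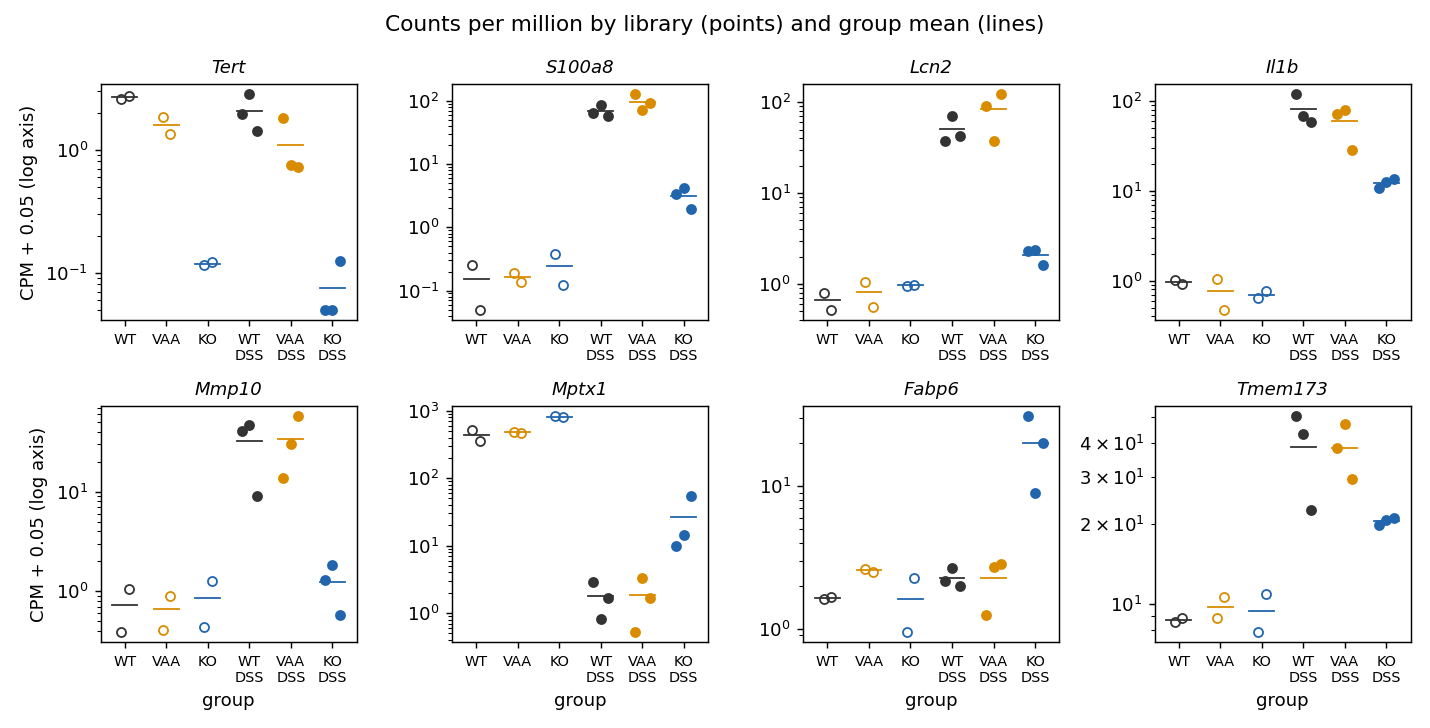
CPM plus a small offset on a log axis for named genes, with points as libraries and lines as group means. Under DSS *S100a8* lay at 69.4 in WT, 97.1 in VAA and 3.14 in KO, and *Tmem173* at 38.7, 38.2 and 20.4.

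In CPM (mean ± SD, n = 3), *S100a8* was at 69.4 ± 15.1 in WT, 97.1 ± 28.1 in VAA and 3.14 ± 1.13 in KO under DSS. *Lcn2* was at 50.1 ± 17.9, 83.4 ± 42.9 and 2.04 ± 0.419. *Tmem173* was at 38.7 ± 14.5, 38.2 ± 8.89 and 20.4 ± 0.652. Log2 CPM values as deposited were shifted against the scaling used here by a median of -0.118 over all genes in KO against WT under DSS and -0.131 in DSS against untreated KO. Tested by limma on the deposited values with Benjamini-Hochberg adjustment, KO against WT under DSS had 375 higher and 856 lower genes, against 561 and 430 in edgeR. DSS in KO had 700 and 1547 by limma against 977 and 885, and the averaged DSS effect 3106 and 4251 against 3936 and 3501. KO against VAA had 717 and 1841 by limma against 1051 and 1644. Exchanging samples between 2 groups of 3 gives an exact permutation *P* no lower than 0.1. In the other splits of the same WT and KO DSS libraries, 0 genes were called against 991, and up to 21 lists against 17, and the 10 splits are too few for a share under 0.05.

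KO against VAA under DSS asked how the knockout differed from the inactive allele in colitis (n = 3 each). *Lcn2* changed by -5.34 ± 0.44, *Retnlg* by -5.29 ± 0.36, *S100a8* by -4.94 ± 0.34, *Chil3* by -4.87 ± 0.53 and *Dio2*, a thyroid hormone activating deiodinase, by -4.92 ± 0.67. *Fabp6* was higher at 3.18 ± 0.45, *Mptx1* at 3.85 ± 0.67 and *Sycn* at 2.86 ± 0.48. *Tert* had 1 count in KO, a ratio of 44.4 (counting interval 7.6 to 1790). *Tmem173* fell by 0.91 ± 0.25, with an edgeR Benjamini-Hochberg adjusted *P* = 0.029, and *Mb21d1* changed by -0.38 ± 0.33, adjusted *P* = 0.52. The *Tmem173* call was lost, with edgeR Benjamini-Hochberg adjusted *P* values given, without VAA DSS replicate 1 (0.055), VAA DSS replicate 2 (0.072), KO DSS replicate 1 (0.093), KO DSS replicate 2 (0.084) and KO DSS replicate 3 (0.075). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1051 genes were higher and 1644 lower, and *Mptx1* had an adjusted *P* = 0.0034. Of these 2695 genes, 541 were still called in a fit of only the groups compared. By that kind of fit KO differed from WT in more genes than from VAA. The count of 2695 genes was 1479 without KO DSS replicate 1, 1380 without KO DSS replicate 2 and 1599 without KO DSS replicate 3.

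In KO against VAA under DSS neutrophil markers fell in 18 of 20 with 2 not passing (19 adjusted over the list alone) at a median of -3.14, and cytokine genes in 17 of 26 with 9 not passing (21 alone) at -2.26, with *Cxcl5* at -2.93 ± 0.35. Camera gave Benjamini-Hochberg adjusted *P* of 4.5e-44 and 7.6e-17 for these lists, and adjusted p = 0.0042 and 0.025 with an estimated correlation. Goblet cell genes rose in 11 of 20 with 9 not passing (15 alone) at 1.10, with *Muc2*, the main colonic mucin, at 1.04 ± 0.15, and regenerative epithelium genes fell in 10 of 20 with 10 not passing (11 alone) at -0.771, with *Ereg* at -2.79 ± 0.29. For these 2 lists camera gave Benjamini-Hochberg adjusted *P* of 2.9e-13 and 1.5e-09, and adjusted p = 0.094 and 0.12 with an estimated correlation. Matrix genes fell in 22 of 25 with 3 not passing (23 alone) at -1.30, with *Tgfbi*, a collagen-binding matrix protein gene, at -1.62 ± 0.23, and enteric neuron and glia genes in 14 of 18 with 4 not passing (15 alone) at -2.57. Camera gave Benjamini-Hochberg adjusted *P* of 1e-14 and 5.1e-10 for matrix and neuron lists, and adjusted p = 0.2 and 0.3 with an estimated correlation, and without VAA DSS replicate 3 their medians were -0.644 and -1.6. The cGAS STING list fell in 5 of 23 with 18 not passing (5 alone), median -0.0207 (-0.107 to 0.0308 with single libraries left out), with a camera Benjamini-Hochberg adjusted *P* = 0.45, and adjusted p = 0.74 with an estimated correlation.

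VAA against WT under DSS asked what the inactive allele, with its lower *Tert* counts, changed in colitis (n = 3 each). *Tmem173* changed by -0.01 ± 0.25 and *Mb21d1* by -0.26 ± 0.32, with edgeR Benjamini-Hochberg adjusted *P* of 0.99 and 0.68. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1 gene. Before adjustment 2855 genes had *P* under 0.05, and DESeq2 called 36 genes and limma 1. The edgeR count was 0 without WT DSS replicate 2, WT DSS replicate 3 or VAA DSS replicate 1, 3 without WT DSS replicate 1 and 848 without VAA DSS replicate 2.

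Wall tissue lists were higher in VAA than WT under DSS at the preset correlation. Medians were 1.38 for enteric neuron and glia genes (10 of 18 adjusted over the list alone), 1.02 for endothelial genes (10 of 15 alone), 0.822 for smooth muscle genes (5 of 15 alone) and -0.603 for proliferation genes, with 0 members of any passing among all genes. Camera gave Benjamini-Hochberg adjusted *P* of 7.6e-07 for each of the first 3 and 3.7e-10 for proliferation, and adjusted p = 0.44 with an estimated correlation. Without VAA DSS replicate 3 these medians were 0.373, 0.248, 0.294 and -0.249. Neutrophil markers had a median of 0.271 and cytokine genes 0.0918, with camera Benjamini-Hochberg adjusted *P* of 0.13 and 0.77. With single libraries left out the neutrophil median ran from 0.11 to 0.476 and the cytokine median from -0.108 to 0.362, and the neutrophil list was called without WT DSS replicate 2, VAA DSS replicate 2 or VAA DSS replicate 3 (camera Benjamini-Hochberg adjusted *P* of 0.031, 0.016 and 0.011). Interferon stimulated genes had a median of 0.225 and the cGAS STING list -0.0709, with camera Benjamini-Hochberg adjusted *P* of 0.13 and 0.68. The interferon stimulated median ran from -0.207 (without VAA DSS replicate 2) to 0.571, and the list was called without WT DSS replicate 1 or VAA DSS replicate 3 (camera Benjamini-Hochberg adjusted *P* of 2.7e-05 and 4.8e-08), while the cGAS STING median ran from -0.202 to 0.0429. In other splits of the same WT and VAA DSS libraries up to 4 genes and 21 lists were called, against 1 and 16.

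KO differences from WT and VAA use the same KO libraries. They shared 441 higher and 301 lower genes where chance gives 33.7 and 40.4, while simulated sharing of libraries gave 0. Their log2 fold changes correlated at 0.728, against 0.506 (0.46 to 0.553) simulated from the shared libraries. The differences of VAA and of KO from WT use the same WT libraries and correlated at 0.0543, against 0.499 (0.453 to 0.539) simulated. The simulation gave each gene 1 spread for all groups, so its values are uncertain where groups differ in spread. Without VAA DSS replicate 3 that correlation was 0.193, against 0.446 simulated. Groups of 3 are too small to split for separate controls.

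The untreated comparisons asked whether genotype mattered before injury (n = 2 each). EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes in VAA against WT, 0 in KO against WT and 0 in KO against VAA. Before adjustment 233, 352 and 401 genes had *P* under 0.05, DESeq2 called 2, 9 and 1, and limma called 0, 1 and 0. Without VAA DSS replicate 1 edgeR called 1 gene in each of the first 2. *Tmem173* changed by 0.16 ± 0.33, 0.11 ± 0.33 and -0.05 ± 0.33, and *Mb21d1* by -0.15 ± 0.41, -0.16 ± 0.41 and 0.00 ± 0.41. The cGAS STING list had medians of 0.0788, -0.00303 and -0.0532, with camera Benjamini-Hochberg adjusted *P* of 0.13, 0.95 and 0.21. The last 2 medians ran from -0.0999 to 0.035 and from -0.199 to -0.0276 with single libraries left out.

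Camera with Benjamini-Hochberg adjustment called 17, 12 and 13 lists in the untreated comparisons at the preset correlation, and 1, 1 and 0 with an estimated one. Plasma cell genes were higher at the preset and the estimated correlation in untreated VAA (median 0.908, 1 of 13 members adjusted over the list alone) and untreated KO (0.811, 3 alone) than in WT. Camera gave Benjamini-Hochberg adjusted *P* of 3.3e-09 and 2.5e-10, and adjusted p = 0.022 and 0.014 with an estimated correlation. *Jchain* changed by 0.91 ± 0.33 and 1.44 ± 0.34, with an edgeR Benjamini-Hochberg adjusted *P* = 1 in each. The VAA and KO medians were 0.574 and 0.438 without WT untreated replicate 1. Without VAA or KO untreated replicate 2 they were 0.322 and 0.377, and KO was at 1.24 without KO untreated replicate 1. Interferon stimulated genes had a median of 0.366 in VAA against WT, with a camera Benjamini-Hochberg adjusted *P* = 2.7e-08, and adjusted p = 0.64 with an estimated correlation. That median was -0.109 (Benjamini-Hochberg adjusted *P* = 0.89 by camera on the edgeR fit) without VAA untreated replicate 1, 0.563 without WT untreated replicate 1 and 0.691 without VAA untreated replicate 2. In KO against WT interferon stimulated genes had a median of -0.258, with a camera Benjamini-Hochberg adjusted *P* = 0.017, and adjusted p = 0.97 with an estimated correlation, lost without WT untreated replicate 1 (-0.0142, 0.79) and KO untreated replicate 1 (-0.145, 0.82), and -0.422 without KO untreated replicate 2. Goblet cell genes had medians of 0.255 and 0.474 in VAA and KO against WT, with camera Benjamini-Hochberg adjusted *P* of 6.6e-05 and 9.6e-14, and adjusted p = 0.64 and 0.13 with an estimated correlation.

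The interaction tests asked whether the DSS response itself differed by genotype. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes for VAA against WT and 0 for KO against WT, with 1259 and 1736 genes at *P* under 0.05 before adjustment. DESeq2 called 0 and 136, and limma 0 and 9. For KO, edgeR called 2 without WT DSS replicate 3, 4 without VAA DSS replicate 2 and 18 without VAA DSS replicate 3. The KO response minus the WT response was -3.71 ± 0.57 for *Saa3*, -5.19 ± 0.90 for *Lcn2* and -2.58 ± 0.45 for *Ereg*, with edgeR Benjamini-Hochberg adjusted *P* of 0.13, 0.2 and 0.2. For *Tmem173* it was -1.03 ± 0.41 and for *Mb21d1* -0.49 ± 0.53, with edgeR Benjamini-Hochberg adjusted *P* of 0.44 and 0.81. The VAA response minus the WT response was -0.17 ± 0.41 for *Tmem173* and -0.11 ± 0.53 for *Mb21d1*, with edgeR Benjamini-Hochberg adjusted *P* of 0.89 and 0.95. Neutrophil markers had a median difference of -2.62 in KO (10 of 20 lower adjusted over the list alone) and cytokine genes -2.49 (13 of 26 lower alone). Members with 3 counts or fewer in an untreated group enter these medians at fitted values, which makes their size uncertain. Camera gave Benjamini-Hochberg adjusted *P* of 6.1e-11 and 1.4e-10 for these lists, and adjusted p = 0.13 with an estimated correlation for each. No interaction list held with an estimated correlation.

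How reads were divided between close relatives, such as *H2-Q7* and *H2-Q6*, was not measured here, so the counts of such genes are less certain. The interval of a log2 fold change had a median width of 0.483 to either side in KO against WT under DSS and 0.587 untreated.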

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

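Of the tests in this part, those of scaling, of fewer leukocytes of every kind and of a uniformly weaker response were chosen only after the result was seen. In the interaction between genotype and DSS, 17 lists differed for VAA against WT and 16 for KO against WT at the preset correlation of camera, and 0 did with an estimated correlation. With an estimated correlation the Benjamini-Hochberg adjusted *P* ran from 0.33 to 0.56 for VAA and from 0.13 to 0.86 for KO. These values are differences of differences, with n = 3 and 2 per genotype.

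For VAA against WT, the DSS response of VAA minus that of WT was above 0 in 4 wall tissue lists, with medians of 1.17 for smooth muscle, 1.22 for enteric neuron and glia, 0.938 for endothelial and 0.711 for matrix genes. Smooth muscle genes fell in both, so this was a smaller fall in VAA, at -1.45 (-2.19 without VAA DSS replicate 3) against -2.58. Immediate early genes were at 0.909 and regenerative epithelium genes at 0.293. Lymphoid lists were below 0, at -1.2 for B cell, -1.01 for plasma cell and -0.471 for T and NK cell genes. Other lists below 0 were adipocyte (-1.76), proliferation (-0.562), goblet (-0.442), oxidative phosphorylation (-0.416), mitochondrial genome (-0.401), fatty acid oxidation (-0.368), stem cell and Wnt (-0.269) and telomerase and telomere genes (-0.153). Without VAA DSS replicate 3 calls were lost for enteric neuron and glia (0.272), endothelial (0.297), T and NK cell (-0.236), regenerative (0.246) and telomerase genes (-0.0241). Calls were lost without WT untreated replicate 1 for T and NK cell (-0.312), B cell (-0.342), enteric neuron and glia (0.853), immediate early (0.24) and telomerase genes (-0.117), and without WT untreated replicate 2 for stem cell (-0.201), regenerative (0.226), adipocyte (-1.73) and telomerase genes (-0.19). They were lost without VAA untreated replicate 1 for regenerative (0.274) and adipocyte genes (-0.562), and without VAA untreated replicate 2 for T and NK cell (-0.167), B cell (-0.0312), stem cell (-0.111) and telomerase genes (-0.0877). They were lost without WT DSS replicate 1 for T and NK cell (-0.379), stem cell (-0.254), adipocyte (-0.277) and telomerase genes (-0.187), without WT DSS replicate 2 for telomerase genes (-0.109) and without WT DSS replicate 3 for regenerative (0.318) and immediate early genes (0.942). They were also lost without VAA DSS replicate 1 for stem cell (-0.221) and adipocyte genes (-1.53), and without VAA DSS replicate 2 for adipocyte (-1.45) and telomerase genes (-0.25). With calls kept, medians moved by over 1.5 times without VAA DSS replicate 1 for telomerase (-0.285), and without VAA DSS replicate 2 for T and NK cell (-0.845), B cell (-2.4) and mitochondrial (-0.695). They moved without VAA DSS replicate 3 for B cell (-0.739), proliferation (-0.252), matrix (0.375), smooth muscle (0.661), oxidative phosphorylation (-0.258), fatty acid (-0.235) and immediate early (0.588), and without VAA untreated replicate 1 for T and NK cell (-1.07), B cell (-1.94), stem cell (-0.409) and telomerase (-0.314). They moved as well without VAA untreated replicate 2 for plasma cell (-0.461) and regenerative (0.537), and without WT DSS replicate 3 for goblet (-0.225) and telomerase (-0.375). They also moved without WT untreated replicate 2 for T and NK cell (-0.747) and B cell (-3.53).

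For KO against WT, inflammatory lists had smaller DSS responses, with medians of -2.62 for neutrophil, -2.49 for cytokine, -0.488 for monocyte and macrophage, -0.472 for NF-kB target and -0.215 for antimicrobial genes. Interferon stimulated genes were at 1.12 and MHC class I genes at 0.434. Smooth muscle genes were at 1.21 and acinar genes at 0.874. The others were red blood cell (-2.64), enteric neuron and glia (-0.985), tuft (-0.725), plasma cell (-0.622), matrix (-0.304), proliferation (-0.284) and regenerative epithelium genes (-0.264). Calls were lost without WT untreated replicate 1 for proliferation (-0.195), acinar (0.824) and red blood cell genes (-2.49), and without WT untreated replicate 2 for enteric neuron and glia genes (-0.622). They were lost without KO untreated replicate 1 for MHC class I (0.24), proliferation (-0.259), enteric neuron and glia (-0.366) and red blood cell genes (-2.43), and without KO untreated replicate 2 for monocyte (-0.134), antimicrobial (0.205) and matrix genes (-0.174). They were lost without WT DSS replicate 1 for red blood cell genes (-1.51), without WT DSS replicate 2 for proliferation genes (-0.184), and without KO DSS replicate 1 or 3 for proliferation (-0.182 and -0.272) and red blood cell genes (-2.21 and -2.39). With calls kept, medians moved by over 1.5 times without KO DSS replicate 1 for interferon stimulated (0.724), regenerative (-0.629) and antimicrobial (-0.373), and without KO DSS replicate 2 for proliferation (-0.444) and matrix (-0.182). They moved without KO DSS replicate 3 for monocyte (-0.782), antimicrobial (-0.392) and matrix (-0.495), and without KO untreated replicate 1 for monocyte (-0.739), regenerative (-0.618), antimicrobial (-0.557) and matrix (-0.518). They moved as well without KO untreated replicate 2 for NF-kB (-0.313) and regenerative (-0.0956), and without WT DSS replicate 1 for antimicrobial (-0.137). They also moved without WT DSS replicate 2 for antimicrobial (-0.377), and without WT DSS replicate 3 for MHC class I (0.287), monocyte (-0.735) and antimicrobial (-0.397). They moved without WT untreated replicate 1 for antimicrobial (-0.331) and neuron (-1.55), and without WT untreated replicate 2 for plasma cell (-0.98), proliferation (-0.637) and regenerative (-0.638). The neutrophil and cytokine calls at the preset correlation held with each library left out in turn.

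Lower neutrophil and cytokine genes in KO than in WT under DSS were weighed against technical and biological explanations. Library scaling is argued against, since the neutrophil median was -2.99 with edgeR factors, -2.99 with DESeq2 size factors and -3 on the deposited log2 values. Fewer leukocytes of every kind are argued against, since T and NK cell genes had a median of 0.48 (quartiles 0.31 to 0.73) with 19 of 22 members above 0, though monocyte and macrophage genes were at -0.51 with 3 of 20 above 0, which leaves fewer myeloid cells open. A response weaker by the same share for every gene, rather than for most, is argued against by MHC class I genes, raised by DSS in VAA and at 0.52 in KO against WT with 4 of 19 members higher, although the list gave adjusted p = 0.33 with an estimated correlation and 7 of the 13 lists raised in VAA were lower in KO and 2 higher. A weaker or otherwise timed response in KO may be the source, and a single harvest day cannot tell which. Of genes DSS raised in VAA 79.9% were lower in KO than in WT, against 13.2% of those it lowered and 52% of other genes. Dose taken, litter, cage and time of peak inflammation stay untested.

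Splits of the same libraries into other groups were counted for each comparison of at least 3 libraries. For KO against WT under DSS the real split called 991 genes and the highest other 0, so 1 of 10 splits was as large, and for lists the values were 17 and 21, with 4 of 10 as large. For KO against VAA they were 2695 and 0 genes (1 of 10) and 19 and 21 lists (5 of 10), and for VAA against WT 1 and 4 genes (3 of 10) and 16 and 21 lists (8 of 10). With 10 splits these are too few for a share under 0.05. For the averaged DSS effect 7437 genes were called against 5357 in the highest other of 100 splits. Only the real split was as large (1 of 100), so chance is unlikely, though not excluded, for the number of genes. For its lists the values were 19 and 26, with 26 of 100 splits as large, so the number of lists is no larger than chance splits often give.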

How the results depend on the processing

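Other settings moved several gene counts by more than 1.5 times. The main fit shared 1 estimate of spread per gene over the groups. VAA DSS replicate 3 lay at a root mean square log2 distance of 0.832 from its group, against at most 0.461 for WT and KO DSS libraries. For DSS in WT, 4642 genes were called, against 1999 without both male libraries and 7588 with library quality weights. For DSS in VAA, 3571 were called, against 1089 in a fit of only the groups compared. For DSS in KO, 1862 were called, against 2986 in a fit of only the groups compared, 1187 with sex as a covariate, 538 without both male libraries and 3047 with weights. The fits without males and with weights were chosen after seeing the data. In fits of only the groups compared DSS called more genes in KO than in VAA, the reverse of the main fit.

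For KO against WT under DSS, 991 genes were called, against 1751 by DESeq2, 2766 in a fit of only the groups compared, 531 without both male libraries and 3503 with weights. For KO against VAA, 2695 were called, against 545 in a fit of only the groups compared. By that kind of fit KO differed from WT in more genes (2766) than from VAA, the reverse of the main fit. For VAA against WT under DSS, 1 was called, against 2 with no expression filter, 36 by DESeq2 and 0 in a fit of only the groups compared. Untreated, edgeR called 0 genes per pair, against 2 (VAA and WT), 9 (KO and WT) and 1 (KO and VAA) by DESeq2, and 1 (KO and WT) by limma. For the KO interaction edgeR called 0, against 5 with no filter, 136 by DESeq2, 9 by limma, 31 in a fit of only the groups compared and 3 with weights. Of 420 list tests, 206 passed at the preset correlation and 20 with an estimated correlation.

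With the replicate number as a block, VAA against WT under DSS called 0 genes, KO against WT 1074 and KO against VAA 2647, and call and direction were the same for 1267 results for named genes, weaker for 15 and stronger for 32. The labels give no ground for pairing equal replicate numbers.

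With each library left out in turn, the count for DSS in WT ran from 1958 (without WT untreated replicate 1) to 6505 (without VAA DSS replicate 3), with 2176 without WT untreated replicate 2 and 2842 without WT DSS replicate 2. For DSS in VAA it ran from 1789 (without VAA untreated replicate 1) to 4902 (without VAA DSS replicate 3), with 2039 without VAA untreated replicate 2. For DSS in KO it ran from 403 (without KO untreated replicate 1) to 3750 (without VAA DSS replicate 3), with 703 without KO untreated replicate 2, 1040 without KO DSS replicate 1, 850 without KO DSS replicate 2 and 1024 without KO DSS replicate 3. The averaged DSS count ran from 6260 to 9156. For VAA against WT under DSS it ran from 0 (without WT DSS replicate 2, WT DSS replicate 3 or VAA DSS replicate 1) to 848 (without VAA DSS replicate 2), with 3 without WT DSS replicate 1. For KO against WT under DSS it ran from 121 (without WT DSS replicate 2) to 2704 (without VAA DSS replicate 3), with 631 without WT untreated replicate 2, 259 without WT DSS replicate 1, 236 without KO DSS replicate 1, 403 without KO DSS replicate 2 and 349 without KO DSS replicate 3. For KO against VAA it ran from 1380 (without KO DSS replicate 2) to 3796 (without VAA DSS replicate 2), with 1479 without KO DSS replicate 1 and 1599 without KO DSS replicate 3. For untreated VAA against WT and KO against WT it ran from 0 to 1 (without VAA DSS replicate 1), and for the KO interaction from 0 to 18 (without VAA DSS replicate 3), with 2 without WT DSS replicate 3 and 4 without VAA DSS replicate 2. List calls ran from 192 to 212.

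The direction of the camera test reversed for 2 list results that passed in one of the fits compared. Proliferation genes in KO against VAA under DSS were at 0.0886 and ran from -0.257 (without VAA DSS replicate 3) to 0.392 (without VAA DSS replicate 2). Interferon stimulated genes in untreated VAA against WT were at 0.366 and ran from -0.109 (without VAA untreated replicate 1) to 0.691 (without VAA untreated replicate 2). Among called lists, medians also changed sign for regenerative genes (0.145 to -0.00238 without KO DSS replicate 1) and acinar genes (-0.083 to 0.0585 without KO untreated replicate 1) in DSS in KO. They did so for MHC class I genes in VAA against WT under DSS (0.276 to -0.00269 without VAA DSS replicate 2), and for antimicrobial genes in KO against WT under DSS (0.00222 to -0.165 without KO DSS replicate 1) and in the KO interaction (-0.215 to 0.205 without KO untreated replicate 2). Of the list results followed and not called with all libraries, 67 were called with at least 1 library left out. In KO against WT under DSS these were 9 lists, among them B cell (0.0771 to -1.22 without KO DSS replicate 1) and adipocyte genes (-0.0621 to 1.22 without WT DSS replicate 1), whose medians changed sign. Without WT DSS replicate 3 they included interferon gamma GTPases (-0.477), red blood cell (-2.55), cGAS STING (-0.23) and acinar genes (0.794), without KO DSS replicate 2 colonocyte genes (0.38), and without KO DSS replicate 1 tuft (-0.478) and fatty acid oxidation genes (0.133). The correlation of the VAA and KO differences from WT under DSS was 0.0543, against 0.00562 over genes with a mean log2 CPM of at least 2 and 0.193 without VAA DSS replicate 3.

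Among results for named genes, call and direction were the same for 1312 with DESeq2 size factors (1 weaker and 1 stronger) and for 1238 with the DESeq2 test (3 weaker and 73 stronger). They were the same for 1270 with limma on the deposited values (22 weaker), 1276 with no filter (7 weaker), 1269 with sex as a covariate (38 weaker) and 1225 without both male libraries (86 weaker). In the fit of only the groups compared they were the same for 1014, weaker for 68 and stronger for 65, and with weights for 1228, 12 and 74.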

Other observations

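Genes were grouped into families by symbol stem, some partly in the planned lists, only after the data were seen. Fisher's test allowed for no correlation between genes. With 270 families of at least 8 tested genes, 9 results passed in the averaged DSS effect and 2 in KO against WT under DSS, with *Cxcl* in both. Proteasome subunits rose in the averaged DSS effect, with 13 of 14 *Psmd* genes higher (92.9% against 22.5% of other genes, Benjamini-Hochberg adjusted *P* = 1.1e-05 by Fisher's exact test, median 0.64) and 10 of 11 *Psmb* genes, 3 of which were in the planned lists. *Psmd3*, a regulatory particle subunit, rose by 0.82 ± 0.08, and *Psmb9*, a subunit of the immunoproteasome, by 2.03 ± 0.23. Of 12 *Cxcl* chemokine genes, 7 of them in the planned lists, 9 rose, and of 8 *Ms4a* membrane protein genes 7 rose, with *Ms4a6c* at 1.49 ± 0.13. Zinc finger genes fell, 145 of 353 *Zfp* genes (41.1% against 19.6%, Benjamini-Hochberg adjusted Fisher *P* = 3.1e-17) at a median of -0.26, and 25 of 48 *Cyp* genes fell (52.1% against 19.9%), with *Cyp3a13*, a drug-metabolising P450, at -1.16 ± 0.18.

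In KO against WT under DSS 2 families were lower more often than other genes. Matrix metalloproteinase genes were lower in 6 of 19 (31.6% against 2.43%, Benjamini-Hochberg adjusted Fisher *P* = 0.0016), with *Mmp8*, the neutrophil collagenase, at -5.11 ± 0.48, *Mmp9*, a gelatinase, at -3.11 ± 0.39 and *Mmp25*, a membrane-bound form of leukocytes, at -1.34 ± 0.35. *Cxcl* genes were lower in 5 of 12 (41.7%), at the same adjusted *P*. The planned lists already held 7 of the *Cxcl* and 7 of the *Mmp* genes.

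Of the tests that follow, those of wall tissue, of depth by tissue lists and of depth by the distance against all other libraries were chosen only after the result was seen. So were the averaging over treatments and the DSS and untreated counts for genes near *Tert*. VAA DSS replicate 3 stood apart from the other 14 libraries, and more muscle, vessel, nerve and connective tissue in that piece may explain it. Its median deviations from the other VAA DSS libraries were 1.23 for smooth muscle, 1.72 for endothelial, 2.12 for enteric neuron and glia and 1.19 for matrix genes, the last being the lowest of the 4, with -1.55 for proliferation genes. Transcript length and GC content are argued against, since the larger correlation of its deviation with either was 0.22. Depth is argued against, since with every library thinned to the lowest total its distance from its group was 0.813 against at most 0.64 in the other 14, and the lowest median of the tissue lists was 1.21, while the limit set beforehand told nothing, as the distance lay within it before thinning too (0.832).

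Genes near *Tert* were asked whether DNA carried along with the knockout allele made them differ. Within 10 Mb, 2 of 102 genes had an unadjusted *P* under 0.01 in KO against WT averaged over treatments (1.96%), against 610 of 16883 elsewhere (3.61%). Fisher's exact test gave *P* = 0.59, so no excess of differing genes was found over that window as a whole. Under DSS alone they were 5 of 102 (4.9%) against 10.5% elsewhere (Fisher *P* = 0.073). The 4 called under DSS were *Nsun2*, *Slc12a7*, *Slc9a3* and *Tppp*, the last at 2.17 ± 0.39 (edgeR Benjamini-Hochberg adjusted *P* = 0.01). In the average, nearby *Slc12a7*, a potassium chloride cotransporter, changed by 0.40 ± 0.10 and *Tppp* by 0.99 ± 0.29, with edgeR Benjamini-Hochberg adjusted *P* of 0.15 and 0.22, and the genetic background of the strains stays open as untested.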
